A study of Rattus norvegicus with 2 samples.

How the data were processed

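Total RNA of RBL-2H3 cells was extracted with Tripure and made into strand-specific TruSeq libraries, per the labels' protocols. The labels give 1 library for normal saline and 1 for PM2.5 plus IgE and DNP-HSA. They do not say whether the saline cells also received IgE and antigen, and they give no dose unit or time. The submitters' processing notes name FastQC, STAR 2.5, Cuffnorm and DESeq 1.22.1 without role or order; the genome build, annotation release and counting settings are not given in the sources used here.

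The authors' deposited values are log2 values per transcript. Raised to the power of 2 and reduced by 1, 100% of them in each library were whole multiples of 1 step, within 1e-06 reads, which reads as a count divided by a size factor, plus 1, on a log2 scale. The size factors were 1.15 for the saline and 0.605 for the treated library, and the read counts behind the values followed from them. The transcripts were protein coding, other Ensembl RNA, Ensembl lncRNA or predicted lncRNA, per the file headers. The authors' deposited p-values and adjusted p-values per transcript were used only as listed; the program that gave them is not given in the sources used here. The design had been fixed for FPKM values or counts before the data were examined; since log2 values were found, all folds use the normalised count plus 1, as deposited. No test with replicates and no count model was run. A further 4 columns of per-sample values repeat these values under other names and were not used.

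Transcripts were summed by gene symbol, giving 15409 symbols; 1276 transcripts without a symbol entered only the isoform and lncRNA counts. 99 symbols joined several gene identifiers. A difference was counted by a rule of size, a log2 fold of at least 1 either way with a normalised count of at least 1 in at least 1 library. Intervals are exact Clopper-Pearson intervals of the treated share of a gene's reads, turned into a ratio; reads are not independent molecules, so they cover counting error only. The precision follows the depth: Egr1 with 616 against 6684 reads had an interval of -2.63 to -2.39 and Gadd45g with 6 against 5 reads one of -0.78 to 3.24. Where a library had 0 reads, the fold is a lower bound against a floor of 3 reads in that library, a normalised count of 4.95 in the treated and 2.6 in the saline library; no bound is given where the other library is under the floor too. The size rule keeps the added 1 for such genes, so that some pass it on few reads; the report states how many in each list came short of 2-fold against the floor, and lists with no such statement held none.

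Before the data were examined, 27 gene lists with 472 genes were fixed. Of these genes 392 matched by symbol and 4 through a synonym in the RefSeq gene table of GRCr8, whose coordinates are not printed; 76 had no match and 19 stand in more than 1 list. Each list's median log2 fold was placed among 10000 random lists of the same size matched on mean expression in 20 bins; the percentile describes these libraries and is not a test. Named genes were chosen by a rule fixed at the same time: all GADD45 and JNK list members; the 12 largest differences each way among symbols with a value of at least 5; per list the 2 largest differences and the 2 highest means; the 6 highest means overall; and the 5 lowest p-values each way in the authors' deposited table. Some genes that the rule takes are not reported here. Other genes named are further members of those lists or are said to be chosen afterwards. Alternatives were another pseudocount, other filters, 3 rescalings, scale factors from the recovered reads (library totals, TMM and the median of ratios over genes with reads in both libraries) for counts of genes, the highest isoform alone and the lncRNA transcripts left out, with a filter of 50, a minimum of 10 reads and a thinned saline library added after the data were examined.

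The procedure was tested on simulated data for this comparison, with Poisson counts for 15409 symbols and 100 symbols changed at each of the log2 folds 1.5 and 3. The changed symbols were drawn only from those with a mean normalised count of at least 50. The procedure put 100% and 100% of them past the size rule, and 96.3% of the intervals held the true ratio. Recovery of changed symbols at lower counts was not simulated. A list of 25 genes with 1 added to their simulated log2 folds lay at percentile 100, and 7% of 200 unshifted lists lay outside the central 95% of random lists. Simulated counts hold no biological spread between cultures. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.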

Results

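Transcript levels were measured by strand-specific RNA sequencing in RBL-2H3 cells, a rat basophilic leukaemia line widely used as a mast cell model. The saline library came from cells given normal saline. The treated library came from cells given fine particulate matter (PM2.5) together with IgE and the antigen DNP-HSA, reagents that crosslink the high-affinity IgE receptor. The labels do not say whether the saline cells also received IgE and antigen. The saline library held 7279671 reads over 20367 listed transcripts and the treated library 3964955, so that the saline library was 1.84 times as deep. Reads were found for 19306 transcripts in the saline library, for 18685 when it was thinned to the depth of the treated one, and for 17164 in the treated library. With 1 library per group no difference has a replicate check and no test between conditions was possible. Values below are log2 folds of the treated over the saline library on normalised counts plus 1. Intervals are exact 95% intervals of the ratio without the added 1, covering counting error only. Folds given as at least are taken against a floor of 3 reads and exceed the exact 95% limits, so the reads also allow smaller folds.

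The comparison addressed which transcripts differ between mast cells given PM2.5 with IgE and antigen and cells given saline, the series title naming reactive oxygen species, Gadd45b and JNK as the axis of interest. Gadd45b (ENSRNOG00000019822), a stress-inducible regulator upstream of JNK and p38 signalling, was higher in the treated library by 2.58 (interval 2.11 to 3.14, 138 against 43 reads). Its transcript was not among those the authors selected, which are described below. Gadd45a differed less, at 0.30 (interval 0.24 to 0.37, 3507 against 5406 reads), and Gadd45g had too few reads for a direction (1.03, interval -0.78 to 3.24, 6 against 5 reads). In the list of GADD45 and JNK pathway genes, 3 of 16 measured members were at least 2-fold higher in the treated library and 1 at least 2-fold lower. Its median log2 fold was 0.022 (-0.45 to 0.30), at percentile 61.2 among random lists matched on expression. The higher ones include Gadd45g, which was at 0.68 with a pseudocount of 5. Brackets after each list's median hold its 95% bootstrap interval over genes. Atf2, a transcription factor phosphorylated by JNK, was at 1.18 (interval 0.94 to 1.43, 314 against 263 reads), while Jun itself was lower at -1.08 (interval -1.16 to -1.003, 1588 against 6403 reads). The kinases themselves stayed within 2-fold, with values for Mapk8 (0.17), Mapk9 (0.30), Map2k4 (0.68), Map2k7 (-0.45) and Map3k7 (0.20). Other members within 2-fold were Map3k4 (-0.68), Map3k5 (-0.63), Mapk8ip3 (-0.62), Dusp8 (-0.27), Dusp10 (-0.43) and Dusp16 (-0.12). With the isoform of highest level taken alone, Mapk9 was at -1.19.

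Immediate early genes and feedback regulators of MAPK signalling formed the list with the lowest median. In this list, 0 of 24 measured members were at least 2-fold higher in the treated library and 17 at least 2-fold lower. The list median lay at -1.63 (-2.54 to -1.01), at percentile 0. Of these members, 24 of 24 had a value below 0. Egr1 (ENSRNOG00000019422), a zinc finger transcription factor induced within minutes of receptor stimulation, was lower at -2.51 (interval -2.63 to -2.39, 616 against 6684 reads). Nr4a3, an orphan nuclear receptor, had 0 against 197 reads and was at least 34.5-fold lower against a floor of 3 reads in the treated library, and Nr4a1 was at least 8.4-fold lower (0 against 48 reads). The AP-1 subunits Fosb and Fos were at -4.16 (interval -4.57 to -3.80, 59 against 2031 reads) and -2.51 (interval -2.87 to -2.18, 77 against 840 reads). Further members on the low side were Egr3 (-4.61), Egr2 (-3.41), Fosl2 (-2.24), Dusp6 (-1.71), Myc (-1.71) and Ier3 (-1.55), and those within 2-fold included Junb (-0.45), Jund (-0.72), Dusp1 (-0.98), Dusp2 (-0.50) and Srf (-0.82). Folds were also related to those of genomic neighbours, with a Spearman correlation of 0.37 across 8607 genes. It set a gene's fold against the median fold of its 10 nearest genes, and genes are not independent replicates. After that relation and gene length were fitted, the median of the list was -1.51 (bootstrap interval over genes -2.63 to -0.91).

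**Figure D1:**
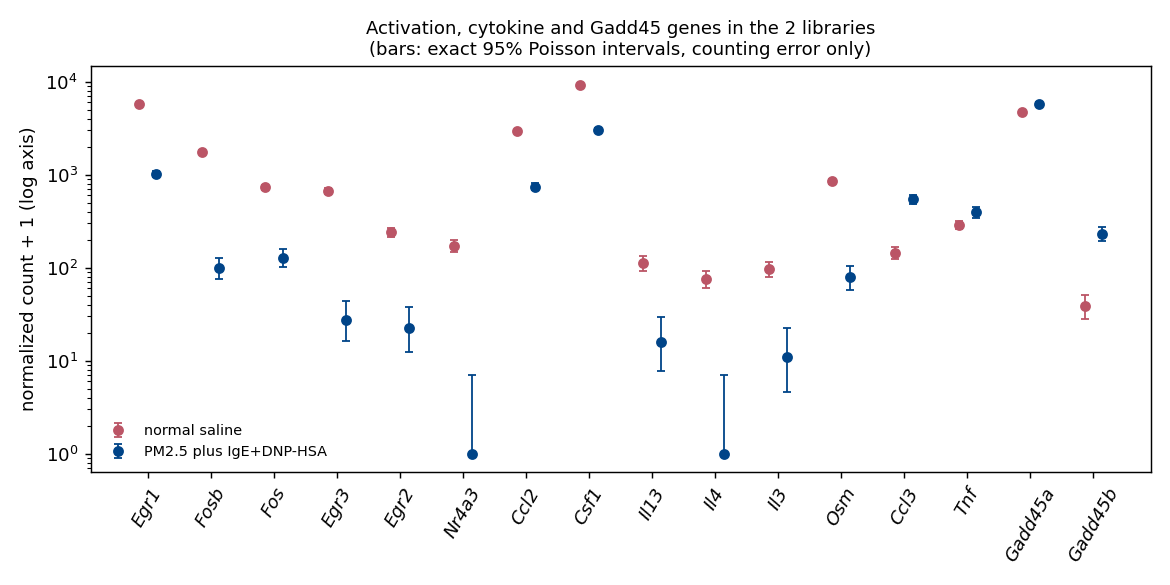
Normalised counts plus 1 (log axis) of immediate early, cytokine and Gadd45 genes in the saline and the treated library, each point 1 library, with bars for exact 95% Poisson intervals that cover counting error only. Egr1, Fosb and Il13 lie lower in the treated library, at log2 folds of -2.51, -4.16 and -2.81, and Gadd45b and Ccl3 lie higher, at 2.58 and 1.91.

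Mast cell cytokines and growth factors went both ways. In that list, 4 of 18 measured members were at least 2-fold higher in the treated library and 9 at least 2-fold lower by the size rule. Of these, 1 had 0 reads in 1 library and came short of 2-fold against the floor. This gave a median of -1.002 (-2.21 to 0.55), at percentile 0.01, or -0.86 with genes at 0 set to their floor. With a filter of 50, chosen after the data were examined, it was -1.78. The lower ones include Areg, whose interval held 0 (-3.73 to 0.55, 3 against 14 reads). Il4 (ENSRNOG00000007624), a cytokine of type 2 responses, had 0 against 86 reads and was at least 15.1-fold lower, and Il13 was at -2.81 (interval -4.05 to -1.92, 9 against 127 reads). The abundant Csf1, the macrophage growth factor, was at -1.60 (interval -1.67 to -1.53, 1839 against 10611 reads), and the chemokine Ccl2 at -1.97 (interval -2.11 to -1.83, 450 against 3354 reads). Lower values were also found for the interleukin-6 family members Lif (-3.10) and Osm (-3.43). The chemokine Ccl3 was higher at 1.91 (interval 1.64 to 2.19, 327 against 165 reads), and Il1b, with 11 against 0 reads, was at least 6.98-fold higher. Tnf was at 0.46 (interval 0.21 to 0.70, 238 against 330 reads) and Tgfb1 at -0.52.

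Genes of mast cell identity and granule content showed no common direction. In that list, 2 of 16 measured members were at least 2-fold higher in the treated library and 2 at least 2-fold lower. Their median log2 fold was 0.0033 (-0.31 to 0.62), at percentile 53.9. Kit, the stem cell factor receptor, was at -0.21 and the transcription factor Gata2 at -0.45. Carboxypeptidase Cpa3 was higher at 1.74 (interval 1.47 to 2.02, 308 against 175 reads), whereas Mcpt8l3 was at least 4.38-fold lower (0 against 25 reads); reads of such protease family members could be split between near-identical copies. Among genes of proximal IgE receptor signalling, 0 of 24 measured members were at least 2-fold higher in the treated library and 2 at least 2-fold lower. The median fold came to -0.30 (-0.50 to 0.061), at percentile 4.18. The lowest members were Pik3cd at -1.52 (interval -1.70 to -1.34, 302 against 1651 reads) and the kinase Syk at -1.14 (interval -1.33 to -0.95, 279 against 1171 reads), while Fcer1a (0.44), Ms4a2 (0.79), Lcp2 (0.20) and Inpp5d (-0.71) stayed within 2-fold. For the exocytosis machinery, 2 of 17 measured members were at least 2-fold higher in the treated library and 0 at least 2-fold lower. Its median log2 fold was -0.12 (-0.39 to 0.28), at percentile 33.5. The higher ones were Rab27b (1.76) and Vamp7 (1.20). Abundant members within 2-fold included Rac2 (0.15) and Coro1a (-0.45). For eicosanoid synthesis, 2 of 14 measured members were at least 2-fold higher in the treated library and 3 at least 2-fold lower by the size rule. Of these, 2 had 0 reads in 1 library and came short of 2-fold against the floor. The list median lay at -0.23 (-0.78 to 0.97), at percentile 24.4, or 0.054 with genes at 0 set to their floor, and 0.054 with a filter of 5. Ptgs2 (ENSRNOG00000002525), the inducible cyclooxygenase, was abundant in both libraries and at 0.056 (interval 0.015 to 0.097, 7419 against 13589 reads). Alox5 was at -0.51 and Cysltr1 at 2.28 (interval 0.71 to 5.17, 10 against 3 reads). Alox12 had 0 against 6 reads.

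Genes linked to particle components, oxidants and metals went both ways. The list for the aryl hydrocarbon receptor, which binds polycyclic hydrocarbons, held targets and also Ahr itself, Arnt, Nfe2l2 and Lgals3. Its members Cyp1a1, Cyp1a2, Aldh3a1 and Ugt1a6 were not measured. In that list, 1 of 8 measured members were at least 2-fold higher in the treated library and 2 at least 2-fold lower by the size rule. Of these, 1 had 0 reads in 1 library and came short of 2-fold against the floor. This gave a median of 0.026 (-1.09 to 0.18), at percentile 63, or 0.063 with genes at 0 set to their floor. Tiparp was higher at 1.47 (interval 1.36 to 1.59, 1547 against 1061 reads) and Ahrr was at -0.80 (interval -0.90 to -0.70, 993 against 3293 reads). Nqo1 was at 0.063, and Cyp1b1 had 0 against 4 reads. For antioxidant genes of the NRF2 programme, 1 of 27 measured members were at least 2-fold higher in the treated library and 1 at least 2-fold lower. Their median log2 fold was 0.14 (-0.13 to 0.47), at percentile 84.5. Mitochondrial superoxide dismutase Sod2 was the higher one at 1.41 (interval 1.19 to 1.63, 421 against 302 reads) and Srxn1 the lower one at -1.79 (interval -3.27 to -0.73, 7 against 49 reads). Abundant members included Fth1 (0.93), Tkt (-0.24) and Hmox1 (-0.13). For NADPH oxidase subunits, 1 of 9 measured members were at least 2-fold higher in the treated library and 2 at least 2-fold lower by the size rule. Of these, 2 had 0 reads in 1 library and came short of 2-fold against the floor. The median fold came to -0.015 (-0.33 to 0.15), at percentile 58.1, or 0.013 with genes at 0 set to their floor. Cybb was at 2.21 (interval 1.28 to 3.48, 29 against 11 reads) and Nox4 had 0 against 5 reads. The abundant GTPases were Rac1 (0.14) and Rac2 (0.15). For metal response genes, 1 of 9 measured members were at least 2-fold higher in the treated library and 1 at least 2-fold lower. Its median log2 fold was -0.041 (-0.35 to 0.60), at percentile 58.3. The metal-sensing factor Mtf1 was at -1.81 (interval -2.27 to -1.39, 52 against 349 reads). The metallothionein Mt2A was at 1.05 (interval 0.02 to 2.21, 17 against 15 reads) and the zinc exporter Slc30a1 at -0.041.

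Members of the stress and inflammatory lists went both ways. For the heat shock list, 3 of 14 measured members were at least 2-fold higher in the treated library and 1 at least 2-fold lower by the size rule. Of these, 2 had 0 reads in 1 library and came short of 2-fold against the floor. The list median lay at 0.40 (-0.46 to 0.93), at percentile 97.2, or 0.27 with genes at 0 set to their floor, 0.20 with a filter of 5 and 0.71 with a filter of 50, the latter chosen after the data were examined. Hsp90aa1 (ENSRNOG00000059714), the inducible cytosolic HSP90, was at 2.41 (interval 2.29 to 2.53, 1989 against 713 reads) and Hspa8 at 1.08 (interval 1.03 to 1.13, 6549 against 5915 reads), while the more abundant Hsp90ab1 was at 0.20 and Hspb1 had 0 against 7 reads. For the unfolded protein and integrated stress response, 1 of 18 measured members were at least 2-fold higher in the treated library and 7 at least 2-fold lower. This gave a median of -0.32 (-1.44 to 0.026), at percentile 3.62. The endoplasmic reticulum chaperones Hspa5 and Hsp90b1 were at 1.96 (interval 1.91 to 2.02, 9002 against 4398 reads) and 0.96, whereas the ATF4 targets Chac1 and Sesn2 were lower at -3.24 (interval -3.59 to -2.93, 82 against 1490 reads) and -2.21 (interval -2.45 to -1.98, 167 against 1472 reads). Among NF-kappaB targets, 4 of 17 measured members were at least 2-fold higher in the treated library and 1 at least 2-fold lower. Their median log2 fold was 0.25 (-0.55 to 0.91), at percentile 92.9. The inhibitors Tnfaip3 and Nfkbia were higher at 1.85 (interval 1.71 to 1.997, 1143 against 603 reads) and 1.14 (interval 1.04 to 1.24, 1844 against 1593 reads), and Ccl2, also in this list, was lower as above. Among p53 targets and apoptosis genes, 2 of 16 measured members were at least 2-fold higher in the treated library and 2 at least 2-fold lower. The median fold came to -0.17 (-0.65 to 0.17), at percentile 29.8, and -0.37 with the filter of 50. Members named by the rule were Ccng1 (1.77), Sesn2 (-2.21), Gadd45a (0.30) and Bcl2l1 (-0.013). For the interferon response, 6 of 15 measured members were at least 2-fold higher in the treated library and 2 at least 2-fold lower by the size rule. Of these, 3 had 0 reads in 1 library and came short of 2-fold against the floor. Its median log2 fold was 0.71 (-0.38 to 1.52), at percentile 99.6, or 0.66 with genes at 0 set to their floor. Several of its members had few reads: Cxcl10 was at least 10.8-fold higher (17 against 0 reads) and Rsad2 was at 3.91 (interval 2.78 to 6.20, 40 against 4 reads). The better covered Stat2 was at -0.18, or 1.73 with its isoform of highest level taken alone.

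Among growth and housekeeping lists, ribosomal proteins had a median above 0 and mitochondrially encoded genes one below 0. For cytosolic ribosomal proteins, 5 of 26 measured members were at least 2-fold higher in the treated library and 0 at least 2-fold lower. The list median lay at 0.47 (0.43 to 0.56), at percentile 99.9. All 26 measured members were above 0. With the totals of the libraries made equal, the median was 0.42, outside that interval, and Rplp0 was below 0 at -0.0058. Examples were Rpl5 (1.27), Rps23 (1.08), Rplp0 (0.047) and Rps2 (0.054). For nuclear-encoded subunits of oxidative phosphorylation, 4 of 22 measured members were at least 2-fold higher in the treated library and 0 at least 2-fold lower. This gave a median of 0.32 (0.10 to 0.63), at percentile 98.8. Examples were Ndufb3 (1.56), Cox6c (1.24), Atp5b (0.022) and Atp5a1 (0.14). For mitochondrially encoded genes, 0 of 12 measured members were at least 2-fold higher in the treated library and 1 at least 2-fold lower. Their median log2 fold was -0.49 (-0.69 to -0.11), at percentile 0.42. Mt-atp6 was at -1.47 (interval -1.54 to -1.39, 1846 against 9717 reads). Mt-co1 was at 0.66, Mt-cyb at -0.54 and Mt-nd3 at -0.79. For the cell cycle, 4 of 26 measured members were at least 2-fold higher in the treated library and 0 at least 2-fold lower. The median fold came to 0.025 (-0.13 to 0.56), at percentile 69.2. The proliferation marker Mki67 was at 2.01 (interval 1.89 to 2.13, 1804 against 852 reads) and Top2a at 1.34 (interval 1.25 to 1.44, 2206 against 1653 reads). Ccne2 was at 2.03 (interval 1.47 to 2.69, 77 against 35 reads) and Ccnd2 at -0.15. For cholesterol synthesis, 2 of 20 measured members were at least 2-fold higher in the treated library and 2 at least 2-fold lower. Its median log2 fold was -0.16 (-0.41 to 0.56), at percentile 24.6. Its members included Idi1 (2.09), Srebf2 (-0.59) and Fdps (-0.35). For glycolysis and hypoxia, 1 of 22 measured members were at least 2-fold higher in the treated library and 2 at least 2-fold lower. The list median lay at -0.03 (-0.22 to 0.27), at percentile 48. Its members included Slc16a3 (-1.68), Adm (1.33), Aldoa (-0.11) and Gapdh (0.11). Among genes often used as references, 2 of 14 measured members were at least 2-fold higher in the treated library and 0 at least 2-fold lower. This gave a median of 0.37 (0.085 to 0.80), at percentile 96.8. Values were Actb (-0.28), Eef1a1 (0.83), B2m (1.38) and Tfrc (1.56).

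**Figure D2:**
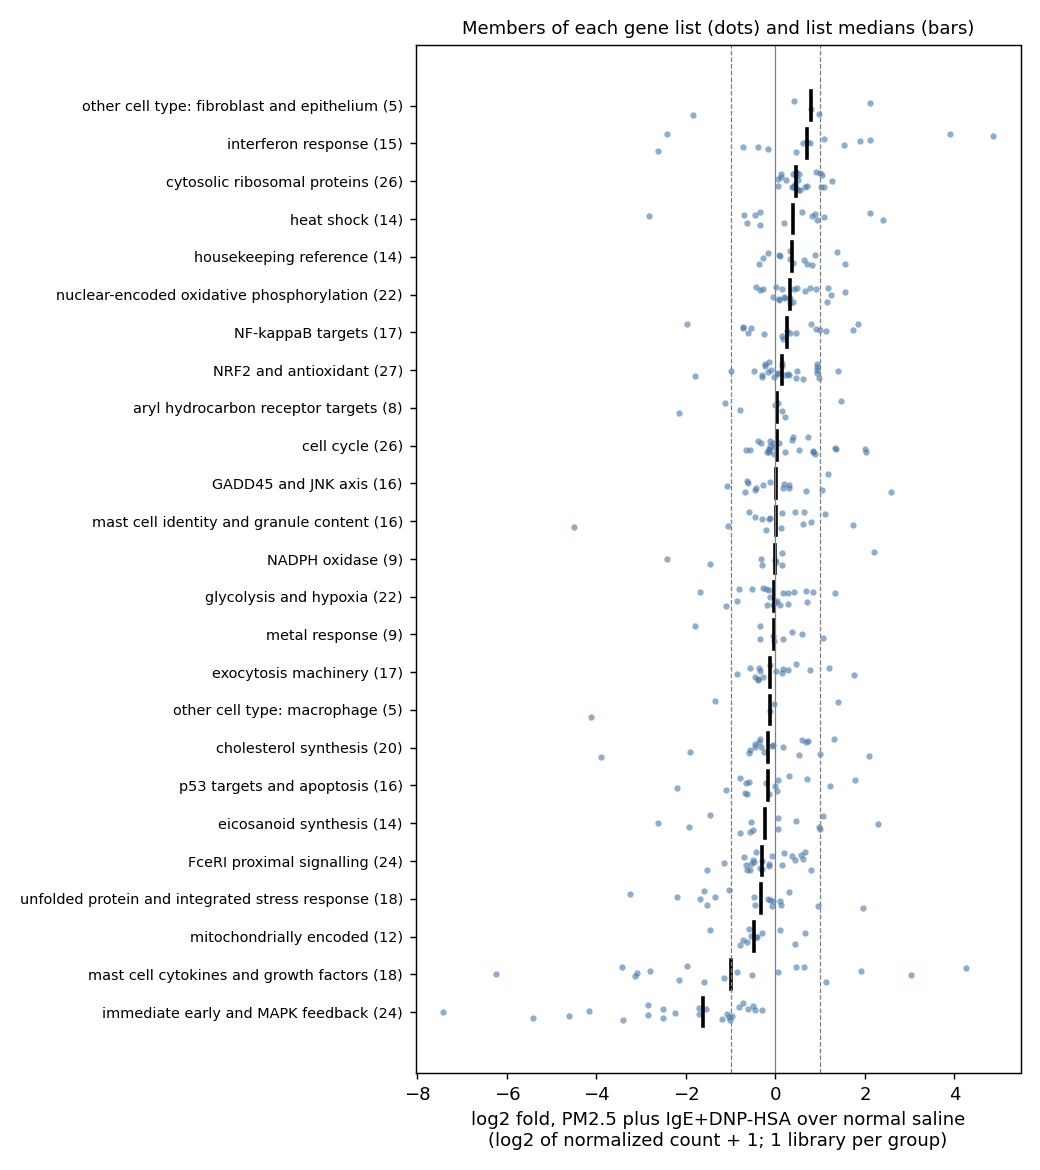
Log2 fold of the treated over the saline library (horizontal axis, normalised counts plus 1) for the measured members of each gene list fixed in advance (dots, vertical scatter for display only), with list medians as bars and measured members in brackets. The immediate early and MAPK feedback list lies lowest, with a median of -1.63, and the cytosolic ribosomal proteins lie at 0.47.

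Few markers of other cell types were measured. None of 10 lymphocyte and none of 10 neutrophil and eosinophil markers was measured. Rpl13, Rplp1 and Mt-co3 were not measured either, so a missing marker does not show that it was not expressed. For macrophage markers, 1 of 5 measured members were at least 2-fold higher in the treated library and 2 at least 2-fold lower. Their median log2 fold was -0.13 (-4.13 to 1.40), at percentile 45.6. Csf1r was at -1.36 (interval -1.55 to -1.18, 286 against 1401 reads) and Lyz2 at 1.40 (interval 0.91 to 1.93, 80 against 57 reads). Cd14 was at -0.033 and Cd68 was at least 3.33-fold lower (0 against 19 reads). For fibroblast and epithelial markers, 1 of 5 measured members were at least 2-fold higher in the treated library and 1 at least 2-fold lower by the size rule. Of these, 2 had 0 reads in 1 library and came short of 2-fold against the floor. The median fold came to 0.79 (-1.85 to 2.11), at percentile 93, or 0.60 with genes at 0 set to their floor, and 1.29 with the saline library thinned, an alternative added after the data were examined. Col3a1 was at 0.41 (interval 0.12 to 0.70, 168 against 241 reads) and Col1a1 at 0.79 (interval -0.28 to 1.95, 15 against 16 reads). Dcn and Pdgfra had 0 against 3 reads and 2 against 0 reads.

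Over all genes, 1826 of 15097 symbols with a normalised count of at least 1 were at least 2-fold higher in the treated library and 2876 at least 2-fold lower, and the median log2 fold was -0.07. Of these, 433 higher and 1320 lower ones had 0 reads in 1 library and came short of 2-fold against the floor. Among 9469 symbols with a normalised count of at least 50, a limit chosen after the data were examined, 707 were higher and 813 lower. Low counts pass the size rule by counting error alone more often. Simulated Poisson counts with no change passed it in 24.1% of 5701 symbols with a mean normalised count under 50. At or above that mean, 0.023% of 8841 symbols passed it. The simulation holds no spread between cultures or libraries, so these shares are not rates of false calls. Its limit was set on the mean, that of the 9469 symbols on the higher library. The largest changes among symbols with a value of at least 5 belonged mostly to symbols with clone or LOC names, whose reads may be split between copies: AABR07037925.2 had 17317 against 0 reads and AABR07037925.1 had 1 against 7563 reads. LOC100910308 had 328 against 0 reads, AABR07064716.2 had 4020 against 1 reads, LOC306079 had 0 against 443 reads and LOC100911837 had 0 against 333 reads. Named genes among the 12 largest differences each way were Hells, a chromatin remodelling factor (47 against 0 reads, at least 29.8-fold higher), Nol8 (32 against 0 reads), Cep290 (25 against 0 reads), Cfap53 (25 against 0 reads), Tuba1c (6 against 1901 reads, -7.24), Ints1 (0 against 207 reads, at least 36.2-fold lower), Ndst2 (0 against 153 reads), Wbp11 (0 against 248 reads) and Nr4a3, given above. The remaining ones higher in the treated library were AABR07035375.1 (55 against 0 reads), LOC100911660 (54 against 0 reads), AABR07006889.1 (29 against 0 reads), AABR07030184.1 (600 against 23 reads) and AABR07030184.11 (590 against 24 reads), and the remaining lower ones AABR07030184.9 (1 against 1040 reads), AABR07030184.10 (1 against 1008 reads), Rn60_10_0621.3 (0 against 218 reads) and LOC100912585 (0 against 182 reads). The 6 most abundant symbols were Mt-co1 (0.66), AC121204.3 (0.035), AABR07070810.1 (0.75), AABR07064724.4 (0.18), Rn7sl1 (0.041) and AABR07057442.2 (0.29).

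At the level of isoforms, 3153 of 19911 transcripts were at least 2-fold higher in the treated library and 4722 at least 2-fold lower, a share of 39.6% against 31.1% of gene symbols. Of these transcripts, 572 higher and 1858 lower ones had 0 reads in 1 library and came short of 2-fold against the floor. In 1023 protein-coding genes whose leading pair of transcripts each had a mean normalised count of at least 50, 180 pairs were at least 2-fold higher for one transcript and at least 2-fold lower for the other. Pairs of unrelated single-transcript genes with like counts gave a median of 12 such pairs over 1000 draws. Past the same count, transcripts of single-transcript genes were at least 2-fold different less often than those of genes with several (14.6% against 31.1%). The compared pairs therefore differ in spread as well.

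The authors' deposited table of selected transcripts held 57 protein-coding transcripts of 53 genes, 18 higher and 39 lower in the treated library. In the authors' deposited table their p-values ran from 0.0345 to 0.0499, and the lowest adjusted value over all transcripts was 0.920. Every one of the 20367 fold values in the authors' deposited table was the saline minus the treated log2 value, so that its positive values are higher in saline. The lowest p-values in the authors' deposited table belonged, for transcripts lower in the treated library, to Ubap2, Dapk1, Vars, Tnfsf8 and Tctn2 (treated over saline -2.67, -2.43, -2.94, -2.37 and -3.12). For transcripts higher in it they belonged to Whsc1l1, Mki67, Mink1, Timeless and Wasf2 (3.45, 2.01, 2.71, 3.02 and 2.94). These are folds of single transcripts. As gene sums, Whsc1l1 (-0.12), Mink1 (-0.60), Timeless (-0.21) and Wasf2 (-0.071) lay below 0, and Mki67, with 1 listed transcript, stayed at 2.01. Of the lower ones, Ubap2 (-0.76) and Vars (-0.66) came short of 2-fold as genes, while Dapk1 (-1.92), Tnfsf8 (-2.37) and Tctn2 (-1.32) did not. Summed per gene, 21 of the 57 kept at least a 2-fold difference in the same direction and 12 had the other sign. Of the 42 transcripts from genes with several listed transcripts, 6 kept it. The 15 from genes with 1 listed transcript kept it by construction, because their gene sum is the transcript itself. Asap1, Whsc1l1 and Sbno2, named after their values were seen, had transcripts selected in both directions. Those with a gene-level difference included Mki67, Smc4, Tnfaip3, Tpr and Son on the higher side and Egr3, Fos, Ccl2, Sesn2 and Tnfsf8 on the lower side, also named after their values were seen. KEGG terms were attached to 31 of the selected transcripts in the authors' deposited table. The most frequent, pathways in cancer, covered 4, of which 1 was higher and 3 lower. Several terms covered 3 each, among them endocytosis, focal adhesion, hepatitis B, TNF signalling and MAPK signalling. No enrichment test was run.

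Long non-coding RNAs took a small part of the reads: predicted ones 3.09% in the saline library (Wilson 95% interval 3.08% to 3.10%) and 2.88% in the treated one (2.86% to 2.90%). Ensembl lncRNAs took 0.308% in the saline library (0.304% to 0.312%) and 0.459% in the treated one (0.452% to 0.465%). Of 1672 lncRNA transcripts, 414 were at least 2-fold higher in the treated library and 644 at least 2-fold lower. Among them, 36 higher and 277 lower ones had 0 reads in 1 library and came short of 2-fold against the floor. The most abundant predicted ones, XLOC.30726.2 and XLOC.377.4, were lower at -1.71 (8111 against 50569 reads) and -1.01. XLOC.17958.3 was higher at 3.59 (interval 3.48 to 3.72), as were both transcripts of XLOC.20464, at 1.43 and 1.84. Their positions and neighbours were not analysed here.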

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

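The filter of 50, the minimum of 10 reads and the thinned saline library were chosen after seeing the data. With a pseudocount of 5, 1023 genes were at least 2-fold higher and 1650 lower in the treated library, and 2049 isoforms were higher and 3072 lower. A filter of 5 left 1894 genes lower, a filter of 50 left 707 higher and 813 lower, and a minimum of 10 reads left 1075 and 1586; each of these filters removes low genes, which pass the size rule most often. The median of the cytosolic ribosomal protein list became 0.42 with equal library totals, which follows from the factor of 0.964 put on the treated library. At an adjusted p-value under 0.01, 0 of the authors' selected transcripts remained in either direction, the lowest adjusted value in the authors' deposited table being 0.920. Of the other values under an alternative, 273 list medians stayed within their bootstrap intervals over genes, 39 counts within 1.5 times, and 745 values of named genes within their counting intervals, while 59 values of named genes left them. None of the named genes past 2-fold changed sign, while 8 within 2-fold did. For those past 2-fold only the highest isoform, in genes with several transcripts, could have changed it. A pseudocount keeps the sign, and the rescalings moved folds by only -0.053 to 0.032. With the highest isoform alone Mapk9 went to -1.19, Mapk8 to -0.058 and Stat2 to 1.73. The 3 rescalings put 36.2% to 40.5% of the calls on the higher side, against 38.8% as reported. Scale factors from the recovered reads left 1869 genes higher and 2850 lower by TMM, and 1887 and 2818 by the median of ratios over genes with reads in both libraries; library totals gave the same as the equal totals above. No paired analysis was possible because each group holds 1 library. Depth limits genes of few reads, such as Gadd45g and Csf2, for which no direction can be given.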

Other observations

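The families and genes in this paragraph and the next, and the tests on library names and on clone names, were chosen after the results were seen. Of 20 gene families sorted by name, among symbols with at least 100 reads, the 12 with the medians of log2 fold farthest from 0 are given, not corrected for the relation with genomic neighbours. Higher medians were found for Cct (7 genes, 0.71), subunits of the cytosolic chaperonin, Cul (8 genes, 0.69), Cenp (12 genes, 0.61), centromere proteins, Rpl (51 genes, 0.54), Rps (45 genes, 0.51) and Lsm (10 genes, 0.50). Lower medians were found for Lrp (8 genes, -0.84), Myo (13 genes, -0.71), Arhgap and Arhgef (32 genes, -0.52), Dock (9 genes, -0.51), Slc (147 genes, -0.40), the solute carriers, and Tuba and Tubb (11 genes, -0.58), the tubulins.

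Among protein-coding genes with over 3 reads in each library and at least 100 in all, Csf3, the granulocyte growth factor, was higher in the treated library at 2.78 (interval 2.26 to 3.43, 123 against 33 reads), as were Upp1 at 2.88 (interval 2.23 to 3.73, 81 against 20 reads) and Id1 at 2.36 (interval 1.98 to 2.79, 191 against 70 reads). Other genes on that side included Casc5 (4.54), Kif20b (2.39), Kif18a (2.30) and Smc4 (2.26). On the lower side were Csrnp1 at -3.31 (interval -3.48 to -3.15, 319 against 6032 reads), the cytokine signalling inhibitor Socs1 at -2.81 (interval -3.69 to -2.13, 16 against 221 reads), the hyaluronan synthase Has3 at -2.94 and Stc2 at -3.02.

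Immediate early and MAPK feedback genes were lower in the treated library, with a median log2 fold of -1.63, although crosslinking of the IgE receptor is known to induce such genes. Scaling is argued against as its cause, since 3 other estimates of scale moved every fold by -0.053 to 0.032 on the log2 scale. The highest median of the list under them was -1.59. Over 100 thinnings of the saline library the highest was -1.56. Thinning keeps the expected value of each gene, so it covers only counting loss at lower depth. Other effects of depth were not tested. A trend with genomic neighbours and gene length stays open in part: the trend gave the list a median of -0.055 and left -1.51, but the interval reached -0.91, short of the bound of -1 set in advance, and base composition of the transcripts was not tested. Swapped library names cannot be told apart from the labels as given. The aryl hydrocarbon receptor list, in which Cyp1a1 and Cyp1a2 were not measured, went both ways around a median of 0.026. Stress and antigen-response genes also went both ways, with Gadd45b (2.58) and Hsp90aa1 (2.41) higher and Il13 (-2.81), Lif (-3.10) and Chac1 (-3.24) lower. The labels state no direction for any of them. The treatment itself, its timing and whether the saline cells met antigen stay open and untested.

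Transcripts of one gene often differed in direction, as among the authors' selected transcripts. The difference in log2 fold within 1023 genes was 1.4 times that between unrelated genes of like counts (0.94 against 0.67, range over 1000 draws 0.59 to 0.76). That is consistent with reads being divided unevenly between overlapping transcripts in the 2 libraries. A change of isoform use between the treatments predicts the same value and was not tested apart. The unrelated genes had 1 listed transcript each. At a mean normalised count of at least 50, 31.1% of transcripts from genes with several passed 2-fold, against 14.6% from genes with 1. Pairs from different genes with several transcripts were not drawn, so the excess is not shown to arise within genes.

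In 20 symbols 1 library held over 100 reads and the other at most 3. Clone or LOC names made up 60% of them (exact interval 36.1% to 80.9%), against 8.46% of all 7757 symbols with over 100 reads in a library, so reads divided between near-identical copies may account for many. The lowest count expected in the near-empty library was 60.9 reads, which follows from the limit of 100 reads, so depth was not tested apart. For the rest, including Nr4a3, Cd151 and Gdf1, no explanation was tested.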
